A study of Mus musculus with 12 samples.

How the data were processed

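Brains without cerebellum and olfactory bulb were taken from CBA/N mice of both sexes after 4 weeks in a winter-like or a summer-like room, all at one clock time in the early afternoon. Per the labels' protocols, poly-A RNA was selected and sequenced as paired-end strand-specific libraries. The tools HISAT and RSEM and the genome build GRCm38.p6 are named in the submitters' processing notes; their versions are not given in the sources used here.

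The authors deposited 1 table of FPKM values, fragments scaled by transcript length and by the mapped fragments of the library, rounded to 2 decimals, for 18962 genes in 12 libraries. One further line of the table held no values and was not used here. Of the gene identifiers, 18836 matched the RefSeq annotation of GRCm38.p6, from which coordinates were taken. A spreadsheet had turned 25 gene symbols into dates, and these were restored from their identifiers. FPKM is scaled within each library, so a change is relative to the rest of that library. Low values of single-transcript genes were whole multiples of the gene's lowest value, within the rounding of both, in 59.1% of 3559 cases against 41.2% by chance, so whole reads could not be recovered and the depth is unknown. FPKM from RSEM can share reads between near-identical genes such as Hspa1a and Hspa1b, or Hba-a1 and its copy, and their separate values are uncertain.

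Values were taken as log2(FPKM + 1), which understates the change of low genes. Genes with at least 1 FPKM in at least 3 of 12 libraries were tested, 13071 in all. One limma model with 4 group means and 8 residual degrees of freedom gave each contrast, with trended empirical Bayes variances, two-sided tests and Benjamini-Hochberg adjustment at 0.05. The contrasts were winter minus summer averaged over both sexes, in males and in females, the female minus the male season effect, and female minus male averaged over both seasons. Gene lists, 42 in all, were tested with camera at a preset correlation of 0.01 where at least 5 members were tested, which held for 34. An estimated correlation, fry, and an exact permutation of the list mean over the 400 assignments balanced within each sex (20 within 1 sex, where p cannot go below 0.1) were alternatives; the permutation was added after seeing the data. R 4.3.3, limma 3.58.1 and statmod 1.5.0 were used, with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 for tables and plots.

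Groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. For each contrast the rule names the called genes with the largest changes, up to 10 in each direction, or 5 for single sexes and the interaction. Their groups must not overlap, or, for season over both sexes and for sex, the fold changes must share a sign in both strata. Where none passed, it names the 5 smallest p-values. It adds up to 4 members with the smallest p of each called list or list with a called member, and 20 genes named in every season contrast whatever their value, with a further 7 for sex. Gene models without a name are not named. The plan did not set 2 options, and both were settled after results had been seen. Camera was run with limma's default constant variance, which called 6 lists for season, and also with a trended variance, which called 8. The default is reported. The sample weights of the plan are limma's default, whose fit stopped before converging; a gene-by-gene version was added because of that and after its calls were known. Alternatives fixed in advance were the pseudocount, the filter, 3 scalings, the variance model, a replicate block, each sex alone and leaving out each library in turn. A correction for transcript GC content (a lowess curve per library with a span of 0.3, on the longest GENCODE transcript, over the 99% of tested genes with a GC value), that correction with a replicate block, and leaving out the 2 libraries with the strongest GC trend were also added after seeing the data.

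The model was tested on simulated data made from the real gene means and residual spreads, with 50 genes changed at each of 4 sizes among 13071. For the season contrast it recovered 46% of genes changed by 0.25 on the log2 scale, 96% at 0.5 and 100% at 1. For the interaction it recovered 2%, 44% and 90%. In single sexes it recovered 24% and 26% at 0.25 and 82% and 78% at 0.5, in males and females. The simulation draws genes independently, which these libraries do not show. Its many changed genes also make the adjusted threshold easier to pass. In the real data 1 season gene was called, and a gene called alone needed about 0.42 at the median standard error. The shares recovered are therefore not the power of the real comparison.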

Results

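RNA was measured in whole brain without cerebellum and olfactory bulb from CBA/N mice, an inbred laboratory strain, of both sexes. The mice were housed for 4 weeks in a winter-like room with 8 h of light and 16 h of dark at 10 °C, or in a summer-like room with 16 h of light and 8 h of dark at 30 °C. The 12 libraries fall into 4 groups of 3, male and female in each season. The groups were read from letter codes in the sample descriptions, with M and F taken as sex, SC as the short-day cold room and LW as the long-day warm room. The labels do not spell these codes out. Y-linked genes matched the sex read from the code in all 12 libraries, and no gene gave an independent check of the season. Light and temperature changed together, so their effects cannot be told apart in this design. The labels do not say that the libraries come from separate animals, so p-values measure the spread between these samples, which may be technical.

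Values were deposited as FPKM for 18962 genes, with sums per library between 358511 and 375041. Between 16859 and 17003 genes lay above 0 in each library. Gapdh, a glycolytic enzyme, was the most abundant gene in each of the 12. Read depth is unknown, so no counting error can be given. Pairs of libraries correlated between 0.9878 and 0.9963 on the log2 scale across genes. Several libraries stood apart within their group. Male winter replicate 1 had the highest levels of cerebellar genes, with the Purkinje cell gene Pcp2, chosen after its values were seen, at 24.86 FPKM there and at 2.05 or less in each other library. Fos, a gene induced by neuronal activity, ranged from 2.92 to 17.95 FPKM. Female winter replicate 1 and female summer replicate 3 had the strongest trends with transcript GC content, with Spearman correlations across genes, which are not independent replicates, of -0.6 and -0.66 between GC content and the library's deviation from the mean of all libraries.

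The first comparison asked which genes differed between winter-like and summer-like housing over both sexes. Mt2, which encodes a metal-binding metallothionein, was higher in winter. It stood at 155 ± 2.56 FPKM in winter males and 104 ± 1.38 in summer males, and at 138 ± 12 in winter females and 120 ± 0.335 in summer females (SD, n = 3 each). It was higher in 6 of 6 winter libraries than in each summer library. The mean change was 0.38 on the log2(FPKM + 1) scale with a standard error of 0.04, or 1.3-fold (limma, adjusted p = 0.00352). Mt2 (gene 17750) lies on chromosome 8 between 94172618 and 94173567 of GRCm38.p6. It was the 1 gene called among 13071 tested. At an unadjusted p under 0.05 there were 638 genes, against 654 that chance gives. At the median standard error a gene would have needed a log2 change of about 0.42 to be called alone.

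**Figure D1:**
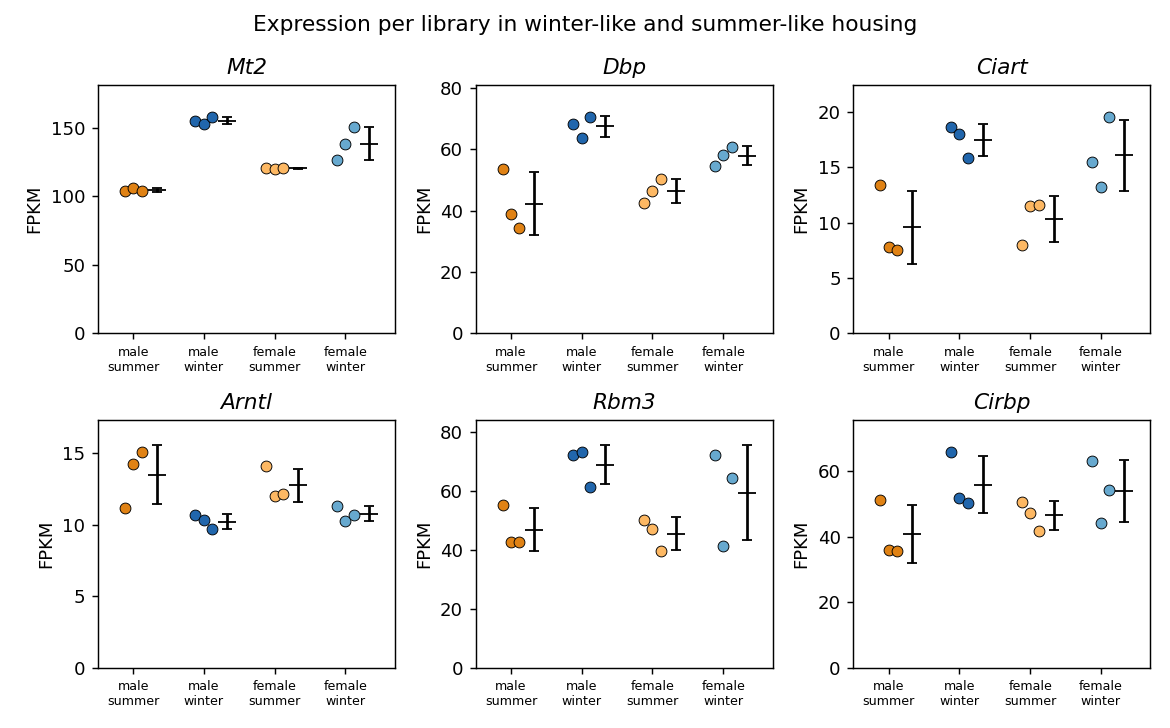
FPKM of 6 genes in each of the 12 libraries, by sex and season, with the group mean and SD (n = 3) to the right of the points and each axis starting at 0. Mt2 passed for season and in males, with means of 155 FPKM in winter and 104 in summer, but not in females, with 138 and 120 (limma, adjusted p = 1); the other 5 genes passed in none of these.

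Clock genes were among those with the smallest p-values after Mt2, although none passed the threshold over all genes. So were Txnip, Gpr17, Avp and Ggcx, chosen for this contrast after their values were seen. They had 0.33 ± 0.06, -0.38 ± 0.07, 0.46 ± 0.09 and -0.23 ± 0.05 for winter minus summer (log2, SE, limma adjusted p = 0.28, 0.295, 0.407 and 0.436). Dbp, a clock-controlled transcription factor, had a winter minus summer value of 0.50 ± 0.09 (log2, SE, adjusted p = 0.28 by limma). Ciart, a repressor within the clock, had 0.72 ± 0.13 (limma, adjusted p = 0.28). Nr1d1, a nuclear receptor that represses Arntl, had 0.32 ± 0.09. Bhlhe41 had 0.25 ± 0.06, and Per2 had 0.10 ± 0.15, or -0.011 without male winter replicate 3 and 0.215 without male winter replicate 1. Arntl, which activates much of this loop, had -0.29 ± 0.07. Of the 19 clock genes, 13 had positive and 6 negative values. Adjusted over the list alone, 6 were called, namely Ciart, Dbp, Nr1d1, Bhlhe41 and Per3 higher in winter and Arntl lower. Over all genes tested, limma called 0 of the list, of which 7 had an unadjusted p under 0.05. Without male summer replicate 1, Dbp and Ciart passed over all genes, with log2 changes of 0.59 and 0.84.

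**Figure D2:**
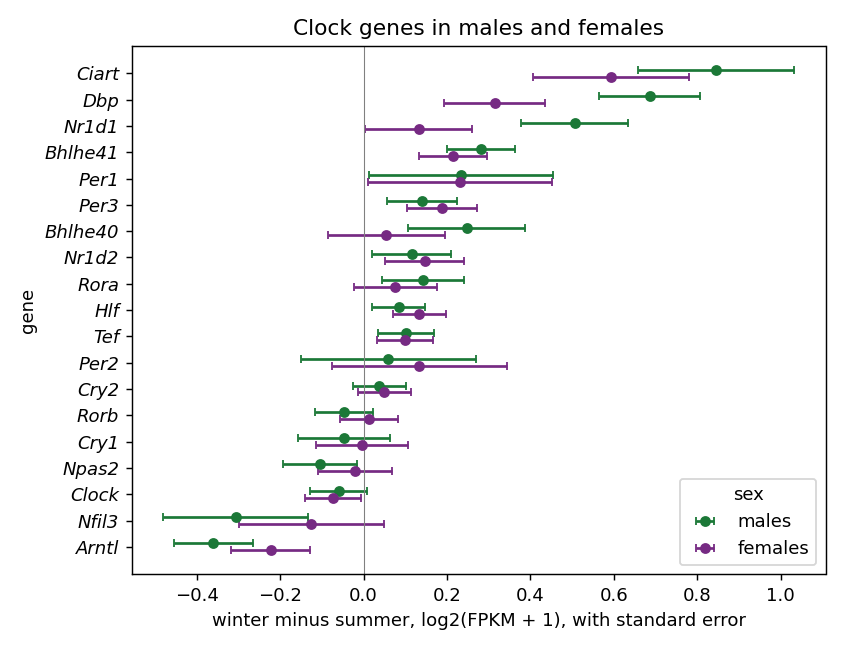
Winter minus summer change of the 19 clock genes on the log2(FPKM + 1) scale, with standard errors from limma, in males and in females. Ciart has the highest values, 0.85 in males and 0.59 in females, and Arntl the lowest, -0.36 and -0.22; none of these passed the threshold over all genes.

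The list test camera, with a preset correlation between genes of 0.01, called 6 of 34 lists for season, and 0 with an estimated correlation. Heat shock and chaperone genes were called lower in winter, with 19 of 19 members negative and a mean of -0.12 (adjusted p = 1.02e-06, and adjusted p = 0.697 with an estimated correlation). Of its members 0 were called by limma over all genes or adjusted over the list alone, and 8 had an unadjusted p under 0.05. Hspb1, a small heat shock protein, had -0.40 ± 0.11, Cryab had -0.25 ± 0.09 (-0.16 without female winter replicate 3), Ahsa1, which activates HSP90, had -0.11 ± 0.04 and Hspa1b had -0.27 ± 0.11. Cholesterol synthesis genes were called higher, with 21 of 21 members positive and a mean of 0.07 (adjusted p = 7.42e-06, and adjusted p = 0.697 with an estimated correlation). Relative to the mean of all libraries, this list stood at 0.053 in winter males and -0.071 in summer males. In females it stood at 0.017 and 0.001 and was not called, so the change lay mostly in males. Insig1, a sterol sensor, had 0.15 ± 0.04, and the enzymes Mvk, Lss and Hmgcs1 had 0.15 ± 0.06, 0.14 ± 0.05 and 0.10 ± 0.05. The clock list was called higher (adjusted p = 0.000131, mean 0.12, and adjusted p = 0.385 with an estimated correlation). Glucocorticoid-responsive genes were called higher (adjusted p = 0.00097, and adjusted p = 0.697 with an estimated correlation), with 11 of 17 members positive. This list holds Mt2, its 1 member called over the list alone, beside Tsc22d3 at 0.20 ± 0.08, Sgk1 at 0.27 ± 0.11 and Arrdc2 at 0.16 ± 0.08 (0.09 without female summer replicate 3). Without female winter replicate 3 the list mean went from 0.092 to 0.047 (adjusted p = 0.0497) and Sgk1 to 0.14. Ribosomal protein genes were called lower (adjusted p = 0.00186, and adjusted p = 0.769 with an estimated correlation), with 65 of 76 members negative, but not without female summer replicate 1 (mean -0.022 in place of -0.035) or male summer replicate 1 (-0.023). Rpl34, Rpl18 and Rpl39 had -0.11 ± 0.04, -0.11 ± 0.05 and -0.13 ± 0.06, and Rpl28 had 0.13 ± 0.05. Mural, fibroblast and meningeal genes were called lower (adjusted p = 0.0414, and adjusted p = 0.769 with an estimated correlation), with 8 of 13 negative; Col3a1, Slc6a13, Col4a1 and Acta2 had -0.16, -0.22 (-0.15 without female summer replicate 1), -0.11 and -0.11. That list was not called without male winter replicate 1 or 3, female winter replicate 3, male summer replicate 2 or female summer replicate 1, with a mean of -0.033 without the last and -0.038 without female winter replicate 3, in place of -0.064.

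Other divisions of the same samples gave a median of 6 called lists, so the number called for season was no larger than relabelled samples give. Male winter replicate 1, the library with the most cerebellar transcripts, had the lowest heat shock mean (-0.16) and male summer replicate 3 the highest (0.25).

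**Figure D3:**
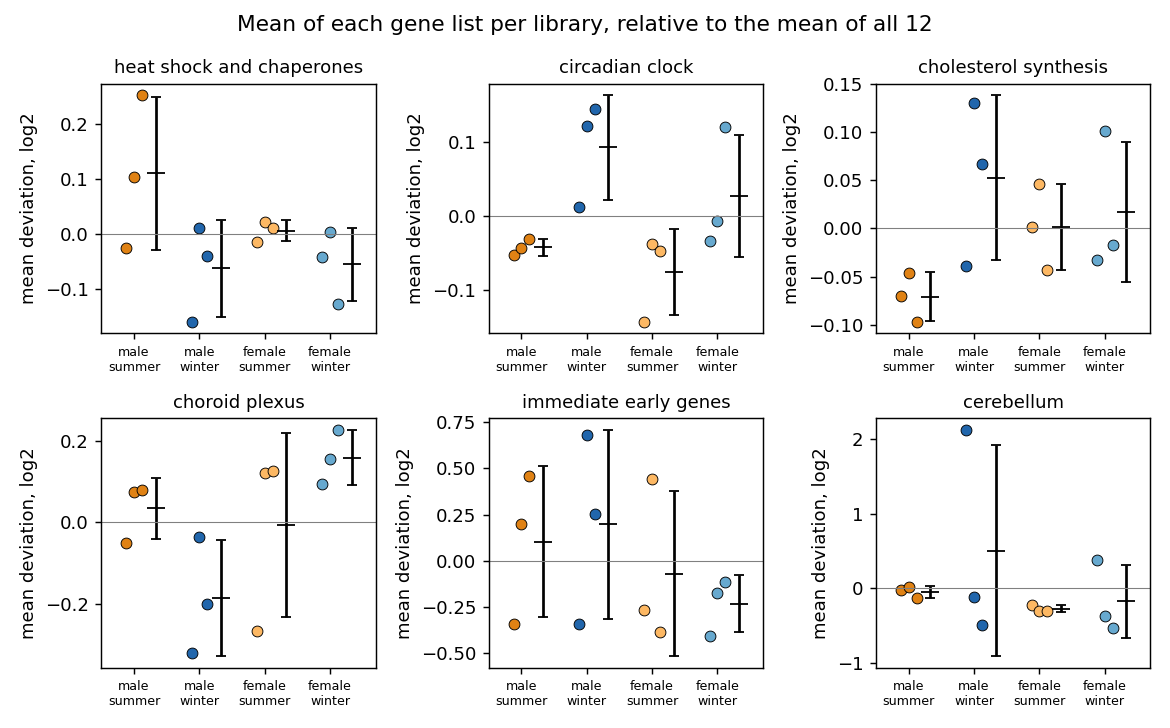
Mean log2(FPKM + 1) of 6 gene lists in each library, relative to the mean of all 12 libraries, with the group mean and SD (n = 3). The heat shock list spans -0.16 to 0.25 with groups that overlap, and the cerebellar list stands at 2.13 in male winter replicate 1 alone.

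The remaining genes fixed in advance were not called for season. The cold-inducible RNA-binding protein genes Rbm3 and Cirbp had 0.45 ± 0.12 and 0.33 ± 0.11 (limma, adjusted p = 0.956 and 0.997), and both were called over their list of 2 alone. The thyroid hormone deiodinases Dio2 and Dio3 had -0.25 ± 0.09 and -0.14 ± 0.09. Tshb, a subunit of thyrotropin, had -0.17 ± 0.11. Tph2, which makes serotonin in the brain, had 0.28 ± 0.23; this rests on female winter replicate 3, with 5.8 FPKM of Tph2 against 0.78 to 2.21 in the other 11 libraries, without which the change was 0.06. The serotonin transporter gene Slc6a4 was below the filter, with 1.05 ± 1.19 FPKM in winter and 0.63 ± 0.282 in summer (SD, n = 6), and 3.46 in female winter replicate 3. Fos had -0.04 ± 0.39, Fkbp5 had 0.07 ± 0.07, Hspa1a had -0.01 ± 0.10 and Hspa5 had -0.20 ± 0.10. Nfe2l2 and its target Hmox1 had -0.02 ± 0.05 and 0.05 ± 0.08. Ttr, Mbp and Gfap, markers of choroid plexus, myelin and astrocytes, had -0.07 ± 0.08, -0.02 ± 0.08 and -0.08 ± 0.06. The haemoglobin gene Hba-a1 had -0.10 ± 0.24. Dio3 was -0.06 without male summer replicate 3, Tshb -0.08 without female summer replicate 1 and Hspa5 -0.12 without male winter replicate 1. Signs turned for Fos (0.27 without male winter replicate 1) and Hba-a1 (0.07 without female winter replicate 1), and for Hspa1a, Nfe2l2, Hmox1 and Mbp between -0.09 and 0.10. Fkbp5 and Gfap were 0.02 and -0.04 without female winter replicate 3, and Ttr -0.01 without female summer replicate 2.

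In males alone, Mt2 was again the 1 gene called, at 0.57 ± 0.06 or 1.48-fold (limma, adjusted p = 0.00196), and 655 genes had an unadjusted p under 0.05 against 654 by chance. Dbp had 0.69 ± 0.12 and Ciart 0.85 ± 0.19. Gpr17, a receptor of oligodendrocyte precursors, had -0.50 ± 0.10, Nr1d1 0.51 ± 0.13 and Hspb1 -0.56 ± 0.15; none of these 5 passed. Without male summer replicate 1, Dbp and Ciart passed as well, and without male winter replicate 2 Zfp967 did, a gene chosen after its values were seen. Camera called 9 lists in males, and 0 with an estimated correlation (adjusted p of 0.382 or 0.91 for each of the 9). Those called higher were clock, cholesterol synthesis, oxidative phosphorylation and cerebellum, and those called lower were heat shock, endoplasmic reticulum stress, oligodendrocyte precursor, mural and choroid plexus genes, with adjusted p from 8.81e-08 to 0.0477. Of the heat shock list 19 of 19 members were negative, with Hspa8 at -0.21 ± 0.08 (-0.13 without male summer replicate 3), and of the cholesterol list 20 of 21 were positive, with Insig1 at 0.22 ± 0.06 and Mvk at 0.24 ± 0.08. Of the choroid plexus list 9 of 10 were negative, with Otx2 at -0.35 ± 0.10 and Ttr at -0.30 ± 0.12 (-0.18 without male winter replicate 1). The endoplasmic reticulum stress mean went from -0.105 to -0.019 without male summer replicate 3 and to -0.03 without male winter replicate 1, and the oxidative phosphorylation mean from 0.037 to 0.012 without male winter replicate 2. The oxidative phosphorylation call was also lost without male winter replicate 1 or male summer replicate 1 or 2. The oligodendrocyte precursor mean went from -0.107 to -0.069 without male summer replicate 2 and to -0.061 without male winter replicate 1, and the clock mean from 0.134 to 0.109 without male winter replicate 3. None of these 4 lists was called then. The heat shock mean went from -0.173 to -0.101 without male summer replicate 3 and was still called. The endoplasmic reticulum stress mean was -0.178 without male summer replicate 1, and the oxidative phosphorylation mean 0.06 without male winter replicate 3. The cerebellar list rested on male winter replicate 1, without which Cbln3, Car8 and Cbln1 went from 0.89, 0.47 and 0.39 to -0.33, -0.07 and -0.05 and the list mean from 0.553 to -0.26; it was not called then, nor without male summer replicate 1. The list mean was 0.866 without male winter replicate 2 and 1.052 without male winter replicate 3. Winter and summer did not overlap for 12.65% of genes, against 10% by chance.

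In females alone, limma called 0 genes, and 227 genes had an unadjusted p under 0.05, fewer than the 654 that chance gives. The named genes with the smallest p-values, none past the threshold, were Ggcx, a vitamin K-dependent carboxylase, at -0.28 ± 0.07, Tmem69 at 0.30 ± 0.07, the neuropeptide gene Avp at 0.53 ± 0.13, Txnip, a glucose-responsive thioredoxin inhibitor, at 0.33 ± 0.08, and Ppp1r35 at -0.42 ± 0.11. Mt2 had 0.20 ± 0.06. With sample weights as limma estimates them by default, 302 genes were called, from a weight fit that stopped before it converged. The gene-by-gene weights called 1 gene, Avp. Camera called 6 lists, and 0 with an estimated correlation (adjusted p of 0.364, 0.578 or 0.885 for each of the 6). It called clock, glucocorticoid-responsive and choroid plexus genes higher and immediate early, microglial and ribosomal protein genes lower, with adjusted p from 8.99e-08 to 0.046. Of the glucocorticoid-responsive list 14 of 17 members were positive, with Sgk1 at 0.43 ± 0.16 and Sult1a1 at 0.39 ± 0.17. These values rest on female winter replicate 3, without which the list mean went from 0.146 to 0.057 (still called), Sgk1 to 0.16 and Sult1a1 to 0.17. Of the ribosomal list 67 of 76 were negative, with Rps12 at -0.19 ± 0.07 (-0.11 without female winter replicate 1). Npas4, an immediate early gene, had -0.36 ± 0.22 (-0.12 without female summer replicate 2, -0.56 without female summer replicate 3). The immediate early mean turned from -0.164 to 0.093 without female summer replicate 2 and was -0.077 without female winter replicate 1, -0.262 without female summer replicate 1 and -0.322 without female summer replicate 3, the last 2 still called. The choroid plexus mean went from 0.166 to 0.035 and the microglial mean from -0.062 to -0.031 without female summer replicate 1, and the clock mean from 0.102 to 0.055 without female winter replicate 3. These 3 lists were not called then, nor the immediate early list without female summer replicate 2 or female winter replicate 1. The microglial list was also lost without female winter replicate 1 or 3 and the clock list without female summer replicate 1. The ribosomal mean went from -0.064 to -0.037 without female summer replicate 1 and was still called. Winter and summer did not overlap for 4.2% of genes, against 10% by chance.

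Whether the season effect differed between the sexes was tested as an interaction. Limma called 0 genes, and 235 had an unadjusted p under 0.05 against 654 by chance. The named genes with the smallest p-values were Mfap2 at -0.53 ± 0.11, Mt2 at -0.37 ± 0.08, Amn at -0.64 ± 0.16, Cfap45 at 0.46 ± 0.12 and Otx2 at 0.54 ± 0.14 (female minus male season effect, log2, SE, limma adjusted p = 0.999 each). The larger Mt2 change in males thus did not pass over all genes, while its unadjusted p was 0.00057 by limma. A difference from females is neither shown over all genes nor excluded. Camera called 9 lists, and 0 with an estimated correlation. Choroid plexus genes had the smallest p (adjusted p = 1.74e-12), with 10 of 10 members positive. Otx2, Sostdc1, Kl and Ttr had 0.54 ± 0.14, 0.70 ± 0.22, 0.45 ± 0.16 and 0.45 ± 0.16, and these 4 were called over the list alone. Its adjusted p was 0.517 with an estimated correlation. Without female summer replicate 1 its mean went from 0.386 to 0.256 and it was still called. A log2 difference of about 0.84 would have been needed for a gene to be called alone.

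Between female and male brains limma called 8 genes, all on the sex chromosomes. The Y-linked genes Eif2s3y, Ddx3y, Uty and Kdm5d were lower in females, at -4.67, -3.91, -2.62 and -2.61 on the log2(FPKM + 1) scale (limma, adjusted p from 1.61e-16 to 4.7e-13). Ddx3y stood at 14.4 ± 0.332 FPKM in winter males and 0.01 in winter females. The X-linked genes Eif2s3x, Ddx3x and Kdm6a, which escape X inactivation, were higher in females by 0.56 ± 0.05, 0.42 ± 0.05 and 0.41 ± 0.05. Mid1, an X-linked ubiquitin ligase gene, was lower in females, at -0.44 ± 0.06 (limma, adjusted p = 0.00613). Kdm5c, also X-linked, had 0.32 ± 0.06 and did not pass (adjusted p = 0.106). Xist was not analysed here. At an unadjusted p under 0.05 there were 1514 genes, against 654 by chance. The 2 libraries with the strongest GC trends are both female, and this excess was not separated from GC content. The number called was 136 without female summer replicate 1, and 1158 and 218 with the default and the gene-by-gene sample weights. Camera called 3 lists, and 0 with an estimated correlation (adjusted p = 0.988 for each of the 3). It called immediate early genes lower in females (adjusted p = 4.13e-05), with Egr3, Egr4, Fosb and Junb at -0.38, -0.59, -0.36 and -0.52. With default sample weights Junb turned to 0.01, and Egr4 and Fosb had -0.25 and -0.21. It called choroid plexus genes higher (adjusted p = 0.00546), with Calml4, Prlr, Aqp1 and Clic6 at 0.27, 0.27, 0.25 and 0.13 (Clic6 0.08 without male winter replicate 1). It called thermogenesis and lipid oxidation genes higher (adjusted p = 0.0224), with Acadm, Pdk4, Hadhb and Ppargc1a at 0.16, 0.14, 0.10 and 0.13. The choroid plexus call was lost without female winter replicate 3 or male winter replicate 1, and the thermogenesis call without any of 6 libraries in turn. The immediate early mean went from -0.301 to -0.18 without male winter replicate 2 and was still called.

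Male and female season effects, which share no library, correlated across 13071 genes at r = 0.202 and rho = 0.205; genes are not independent replicates. Of 655 genes with an unadjusted p under 0.05 in males, 464 (70.8%) had the same sign in females. Of 227 such genes in females, 150 (66.1%) had the same sign in males. Other divisions of the same samples reached r = 0.361.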

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

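The tests of GC content and of the amount of choroid plexus were chosen after the results were seen. Camera with a preset correlation called 9 gene lists on the interaction of season and sex, and 0 with an estimated correlation (adjusted p from 0.517 to 0.854 for the 9). Each is given as the mean of female minus male season effects on the log2 scale. Choroid plexus genes had the highest, 0.386 (camera, adjusted p = 1.74e-12), with a season mean of -0.22 in males and 0.166 in females. The positive mean in females rests on female summer replicate 1, without which it was 0.035 and the interaction 0.256. The adjusted p was 0.517 with an estimated correlation, and the exact permutation p of the list mean was 0.035, or 0.932 adjusted over the 34 lists. Mural, fibroblast and meningeal genes had 0.169, cholesterol synthesis genes -0.108, heat shock genes 0.111 and ribosomal protein genes -0.057. Oxidative phosphorylation genes had -0.058, immediate early genes -0.256, serotonin genes 0.14 and oligodendrocyte precursor genes 0.087. With 1 library left out, these calls were lost for oxidative phosphorylation (-0.018 without female summer replicate 1, -0.037 without female winter replicate 3, -0.033 without male winter replicate 2) and for immediate early genes (0.001 without female summer replicate 2, -0.169 without female winter replicate 1, -0.031 without male summer replicate 1, -0.014 without male winter replicate 2). The immediate early mean was also -0.524 without male winter replicate 1, -0.434 without male summer replicate 3 and -0.414 without female summer replicate 3, and the oxidative phosphorylation mean -0.093 without female summer replicate 3. Calls were lost for serotonin genes (0.07 without female winter replicate 3, 0.094 without female summer replicate 1, 0.126 without male winter replicate 2) and for oligodendrocyte precursor genes without any of 5 libraries in turn, namely female summer replicate 3 (0.073), female winter replicates 2 (0.062) and 3 (0.072), male summer replicate 2 (0.049) and male winter replicate 1 (0.041). They were lost for heat shock genes (0.04 without male summer replicate 3, 0.063 without male winter replicate 1) and for ribosomal genes (-0.031 without female summer replicate 1 or male winter replicate 2, -0.036 without female winter replicate 3). The cholesterol mean was -0.069 without male winter replicate 2 and the heat shock mean 0.179 without male summer replicate 1, both still called.

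Chance could not be excluded for this number of lists: the real split called 9 and the highest of the others 14, and 30 of 100 splits called as many. For interaction genes the comparison decides nothing, since the real split called 0 and each of 100 splits (100 of 100) must call at least that; the highest other called 21.

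Against GC bias of single libraries as the whole cause of the choroid plexus pattern, the changes after GC correction had a slope of 0.98 (SE 0.018) on those before. The amount of choroid plexus in each sample may vary with dissection. Within groups, Ttr and the mean of the other members moved together with r = 0.62 and rho = 0.53 over 12 libraries (permutation p = 0.181 and 0.191, adjusted 0.181 and 0.191 over 3 relations), and r was 0.45 without the 2 farthest libraries. The relation did not pass its permutation test. It could arise with either cause, so it cannot tell dissection from a difference between the sexes in the response to season. The amount of choroid plexus was not measured, and the 2 cannot be told apart here.

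Otx2, a choroid plexus transcription factor, and Cfap45, a gene of cilia, were lower in each winter library than in each summer library of males and higher in each of females. Their interactions were 0.54 and 0.462 (limma, adjusted p = 0.999 each), so the gene-level test of the difference did not pass. Of the genes tested, 15 separated in opposite directions, 0.11% against 0.5% by chance.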

How the results depend on the processing

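The GC correction, alone and with the block, the omission of the 2 libraries with the strongest GC trend, the gene-by-gene weights, the permutation, the mixed test of fry, the trended camera variance and the omission of libraries for lists in males, females and sex were chosen after the results were seen. Mt2 was called for season and in males in every setting run. The interaction gave 0 genes in each. The agreement between sexes stayed between 0.168 and 0.228 in the settings with all libraries. Named genes kept their direction and side of the threshold in 5260 of 5386 combinations of gene, contrast and setting, 37 passed the threshold that had not, 1 no longer passed and 88 changed sign. Causes were not tested unless said. Unknown depth limits low genes by an amount that cannot be given.

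Default sample weights, whose fit stopped before converging, called 7 season genes (Mt2, Avp, Dbp, Ddx49, Rsph9, Tspan4 and Txnip, the last 4 and Avp chosen after their values were seen), 302 in females and 1158 for sex. Gene-by-gene weights called 3 (Mt2, Avp, Dbp), 1 (Avp) and 218. GC correction called 2 season genes, Mt2 and Avp. The 8 sex genes were kept in each setting except Mid1, which was not tested with the stricter filter and had an adjusted p of 0.0616 by limma without the 2 GC-trend libraries.

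The replicate numbers did not pair the samples: 6 of 18 same-number pairs correlated above 0.1, from -0.23 to 0.24, and 4 of 12 libraries were closest to their own number. With the replicate block 1 season gene, 12 sex genes, 8 season lists and 12 interaction lists were called. With GC correction and the replicate block, 4 season genes (Mt2, Avp, Gpr17, Txnip) and 13 sex genes were called, Gfap in females had 0.001 and Dio3 in the interaction 0.024.

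Leaving out 1 library at a time gave 1 to 3 season genes, 1 to 3 in males, 0 to 1 in females and 8 to 136 for sex. The 3 were Mt2, Dbp and Ciart, without male summer replicate 1; without male winter replicate 2 there were 2, Mt2 and Zfp967. The 1 in females was the gene model Gm13306, chosen after its values were seen, without female summer replicate 2. The 136 came without female summer replicate 1.

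Lists called fell from 6 for season and 9 for the interaction to 0 and 0 with an estimated correlation, 0 and 0 with the directional test of fry, and 0 and 0 with the exact permutation, whose smallest adjusted p for season was 0.17. That is the lowest value 1 list alone can reach, as the permutation p cannot go below 0.005 before adjustment over 34 lists. A lone list could thus not have been called by permutation. The mixed test of fry, for changes in either direction, called 3 and 0; the 3 were clock and glucocorticoid-responsive genes (adjusted p = 0.0126 each) and oligodendrocyte precursor genes (adjusted p = 0.0318). It called 2 lists in males, 0 in females and 1 for sex. Trended variance called 8 and 9. In the 28 camera settings that keep the preset correlation, cholesterol, clock, glucocorticoid-responsive and heat shock genes were called for season in all. Ribosomal genes were not in 2, without female summer replicate 1 or male summer replicate 1, nor mural genes in 8. For the interaction, choroid plexus and cholesterol genes were called in all 27 and 28 settings run with the preset correlation, and the other 7 lists were lost in 1 to 6 of 28.

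None of the genes whose sign changed had passed the threshold. Their log2 changes were as follows. With rescaling to TPM, Gfap in females had 0.002, and with quantile normalization Mbp for season had 0.01. With default weights, Junb for sex had 0.01, Fkbp5 in males 0.021, and in females Dio3 0.017, Hspa1a -0.095, Nfe2l2 -0.005, Hmox1 0.01 and Ttr -0.117. In the interaction Dio3 had 0.078 and Hspa1a -0.04. With gene-by-gene weights, Mbp for season had 0.003, Fkbp5 in males 0.022, Hspa1a, Hmox1 and Ttr in females -0.043, 0.005 and -0.052, and Dio3 in the interaction 0.043. With GC correction, Gfap in females had 0.001 and Dio3 in the interaction 0.024. Without the 2 GC-trend libraries, Hba-a1 had 0.217 for season and 0.212 in females, Hmox1 in females 0.077 and Dio3 in the interaction 0.065.

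With 1 library left out at a time, the ranges for season were -0.011 to 0.215 for Per2, -0.291 to 0.268 for Fos, -0.089 to 0.039 for Hspa1a, -0.055 to 0.001 for Nfe2l2, -0.013 to 0.1 for Hmox1, -0.068 to 0.039 for Mbp and -0.344 to 0.067 for Hba-a1. In males they were -0.069 to 0.771 for Car8, -0.047 to 0.663 for Cbln1 and -0.334 to 1.654 for Cbln3, the lowest of each without male winter replicate 1, the library with the most cerebellar transcripts. In males they were also -0.229 to 0.036 for Dio3, -0.023 to 0.144 for Tshb, -0.157 to 0.296 for Per2, -0.17 to 0.948 for Fos, -0.079 to 0.046 for Fkbp5, -0.231 to 0.025 for Hspa1a and -0.125 to 0.017 for Mbp. In females they were -0.68 to 0.007 for Egr2, -0.04 to 0.282 for Per2, -0.763 to 0.141 for Fos, -0.051 to 0.142 for Hspa1a, -0.028 to 0.084 for Nfe2l2, -0.179 to 0.041 for Hmox1, -0.089 to 0.124 for Mbp and -0.069 to 0.077 for Gfap. In the interaction they were -0.366 to 0.03 for Rbm3, -0.191 to 0.074 for Dio3, -0.161 to 0.291 for Per2 and -0.042 to 0.171 for Mbp.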

Other observations

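The tests of GC content, clock phase, arousal, temperature state, 1 library and the splits for the agreement between sexes were chosen after the results were seen. Most cell type lists did not pass for season by camera. Myelin and oligodendrocyte genes had a mean log2 change of 0.002 over 16 members (adjusted p = 0.968), astrocyte genes -0.022 over 12 (0.604), microglial genes -0.042 over 13 (0.0977) and endothelial genes -0.039 over 11 (0.515). Pan-neuronal genes had 0.011 (0.802) and inhibitory neuron genes -0.014 (0.802). Photoperiod and thyroid hormone genes had -0.086, with 10 of 12 members negative (0.163), and hypothalamic neuropeptides 0.052 (0.226), of which Avp alone was called over the list alone. Glycolysis genes had 0.032, with 14 of 16 positive (0.0668). Retinoid signalling genes had 0.003 (0.824).

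Libraries of one group differed in several gene groups. The immediate early list, relative to the mean of all libraries, stood at 0.68 in male winter replicate 2 and -0.341 in male winter replicate 1, and at 0.445 in female summer replicate 2 and -0.385 in female summer replicate 3. Egr2 ranged from 0.46 to 4.84 FPKM in winter males. Hba-a1 stood at 66.14 FPKM in female winter replicate 1 and 150.16 in female winter replicate 2. The first principal component held 27.8% of the variance, and its loadings correlated with GC content across genes at rho = -0.75.

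Of the 19 clock genes, 11 driven by Arntl and Clock and the 3 genes Arntl, Clock and Npas2 differed in their season change by 0.392 on the log2 scale. These 14 were grouped after their values were seen and Cry1, Cry2, Nfil3, Rora and Rorb were left out, so this difference is a description and no test of it is given. The mean of the whole list had an exact permutation p of 0.005, the smallest the assignments can give, and 0.17 adjusted over the 34 lists. At that limit 1 list alone cannot go below 0.17 after adjustment, so the adjusted value decides nothing. A candidate explanation is another phase of the clock at sampling, since all brains were collected at one clock time and the time of lights-on is not given in the sources used here. Phase at sampling and season cannot be told apart, because the design confounds them. GC bias is argued against as the whole cause, with a slope of 0.99 (SE 0.013) of corrected on uncorrected changes.

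Heat shock genes were called lower in winter by camera with a preset correlation, with 19 of 19 members negative, and not with an estimated correlation (adjusted p = 0.697) or by permutation (0.659 adjusted), so the pattern itself is uncertain. GC bias is argued against as the whole cause, with a slope of 1.01 (SE 0.026). Arousal or handling before sampling is open. Within groups the immediate early and heat shock means moved together with r = 0.7 and rho = 0.66 over 12 libraries (permutation p = 0.0255 and 0.0563, adjusted 0.0764 and 0.0891 over 3 relations). This relation did not pass the correction and fell to r = 0.45 without the 2 farthest libraries. Leaving out extreme libraries narrows the range, so this drop does not show whether the relation rests on them. By season the immediate early mean was -0.018 in winter and 0.018 in summer (SD 0.412 and 0.396). In males it was higher in winter (0.196 and 0.105), opposite to the heat shock mean (-0.062 and 0.11). In females both means were lower in winter (-0.232 and -0.069, and -0.055 and 0.007). The immediate early values of winter and summer overlapped in each sex, so these means do not decide it. The temperature of single animals is open, with r = -0.63 and rho = -0.66 between the mean of Cirbp and Rbm3 and the heat shock mean (permutation p = 0.0872 and 0.0594, adjusted 0.131 and 0.0891; r = -0.48 without the 2 farthest). Without male summer replicate 3 the list mean was -0.081 in place of -0.117 (SE over members 0.02, and members are not independent). The list was still called by camera with a preset correlation (adjusted p = 0.000148), so that call does not rest on this library alone. How much this library adds to the size is open. The housing temperature itself is untested apart from day length.

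Other splits of the samples were counted for each result. For season genes the real split called 1 and the highest other 17, and 7 of 100 splits called as many, so chance is not excluded for that count. For season lists the real split called 6 and the highest other 14, and 60 of 100 splits called as many, so chance is not excluded. For the correlation of season effects between sexes the real value was 0.202 and the highest other 0.361, and 11 of 100 splits gave as large a value, so chance is not excluded. For sex genes the real split called 8 and 2 of 100 splits called as many. That outcome was set in advance for the Y-linked genes, which are nearly absent in females. The comparison thus does not exclude chance for the other sex genes. The other split called 588. It exchanges male summer replicate 3 and female summer replicate 1 and has mean first component scores of 6.26 and -6.26, which points to a structure of the samples. Loadings of that component correlated with GC content across genes at rho = -0.75. Its scores ran from -9.35 to 1.06 in males and from -4.66 to 15.04 in females, so sex was not balanced over it. The 1514 genes at an unadjusted p under 0.05 for sex were not separated from this component. Within males (real 1, highest other 0; 1 of 10 splits) and within females (real 0, highest other 3; 10 of 10) the splits are too few for a share under 0.05.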
